A study of Mus musculus with 12 samples.

How the data were processed

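The 12 libraries were made by ACT-seq from permeabilized lung endothelial cells, with antibody, Protein A and Tn5 complexes, and were sequenced as read pairs, per the labels' protocols. They fall into 6 groups by genotype and mark, with 2 replicates each, as the sample titles give them. No label says whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Replicates of each group differed by more than counting noise in a chi-square comparison, and all 12 were kept as separate samples.

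The deposited table holds raw whole-number counts per region and library, without normalization. Per the submitters' processing notes, Subread, edgeR 4.0.16, R 4.3.3 and ChIPseeker 1.38.0 were used, and the builds GRCm39 and mm10 are named, with no role or order. The aligner, the peak caller and its settings, the removal of duplicates and the treatment of reads that overlap several regions are not given in the sources used here. Each region is named by a list number from 1 to 12 and a running number, with no coordinates and no gene. The list numbers were read as the library numbers of the labels, and in 12 of 12 lists the library of that number had the highest share of its counts. In this way each list is taken as the regions called in 1 library, which favours that library in its own list, and for this reason values are also given for the lists of the other marks. Of all regions, 560127 (47%) had no count in any library.

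Depth ran from 396441 to 4242014 counts per library. Wilson 95% intervals of shares and the floor of 3 counts cover counting error only, since reads amplified by PCR are not independent molecules. Precision is set by counts per region: among regions with counts in the library's own list, the median count ran from 4 in 3 of the H3K4me3 libraries to 40 in WT H3K23ac replicate 2.

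Regions were tested for each mark in its 4 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with TMM factors, filterByExpr at a minimum count of 10, and Benjamini-Hochberg adjustment, with a threshold of 0.05. Fold changes are CSE-KO over WT. CPM values, counts scaled to a common library size, use the counts in tested regions times the TMM factor as that size. A fold against a group without counts is given as a bound over a floor of 3 counts in the group. Medians over lists came out the same with such regions set to their bound as with the fitted folds. The difference between marks was tested as a contrast of contrasts in a model of all 12 libraries. Agreement between marks is the correlation of log2 fold changes over regions tested in both, with intervals from 1000 bootstrap draws of regions. The test was checked on simulated data with 200 changed regions per mark, 50 for each of the folds 2, 4, 8 and 16. It made 0 false calls for H3K23ac, 8 for H3K27ac and 7 for H3K4me3. DESeq2 1.42.0 served as the second tool, and summaries used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

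Tests, samples, covariates and alternatives were chosen before the data were examined. The alternatives were DESeq2 size factors, total counts, no filter, a filter at the median CPM, the DESeq2 Wald test, all 12 libraries in a model, the replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn. Regions of the other marks' lists and a joint genotype term over H3K27ac and H3K4me3 were added after the data were seen.

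The difference and the agreement between marks were planned on promoters and were run on regions. Models of the 8 libraries of 2 marks were added after the data were seen. The plan also held tests of promoters, of gene lists, of the gene Cth, of promoter against distal regions and of autosomes alone. These need a position or gene for each region and were not analysed here, so the knockout itself was not checked in these libraries. The plan named genes, and its rule could not be applied to regions without genes. In its place, and after the data were seen, regions past the threshold were named, and for a mark with none the region of lowest p, except that none is named for H3K23ac. At most 2 names are printed per direction, and the regions of the interaction test and of the joint genotype term are described by their list.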

Results

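Histone marks were profiled in endothelial cells isolated from mouse lung. The samples are labelled wild type (WT, negative for the Cre recombinase) or CSE knockout (CSE-KO, Cre-positive). An effect of Cre itself cannot be told apart from that of the knockout in this design. CSE, cystathionine gamma-lyase, is the enzyme encoded by Cth that releases cysteine from cystathionine. The profiling used ACT-seq, in which an antibody joined to Protein A and the Tn5 transposase inserts sequencing adaptors into chromatin that carries the mark. The marks were acetylation of lysine 23 (H3K23ac), acetylation of lysine 27 (H3K27ac, found at active promoters and enhancers) and trimethylation of lysine 4 (H3K4me3, found at active promoters). The design has 12 libraries, 2 per genotype and mark, and asks whether loss of CSE changes the marks and whether the 3 marks change alike.

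Depth differed between marks and between libraries. Total counts were 1569853 and 1848702 in the WT H3K23ac libraries and 1908675 and 1466588 in the CSE-KO H3K23ac libraries. The H3K27ac libraries held 1351854 and 1110254 counts in WT, and 4242014 and 1286295 counts in CSE-KO, so that CSE-KO H3K27ac replicate 1 was the deepest of the 12. The H3K4me3 libraries were the shallowest, with 396441 and 563330 counts in WT and 563755 and 434944 counts in CSE-KO. Counts were spread over 1192075 regions in 12 lists, of which 631948 had a count in at least 1 library and 2916 had counts in all 12. The highest count of a region in a library was 899.

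The H3K23ac lists had a mean length of 108165 ± 56250 regions in WT and 104112 ± 9733 in CSE-KO (SD, n = 2 each). For H3K27ac the lists held 108450 ± 26630 regions in WT and 175605 ± 55610 in CSE-KO, and for H3K4me3 50256 ± 12960 and 49451 ± 1489 (SD, n = 2 each). The H3K27ac lists held 89618 and 127282 regions in WT and 214924 and 136286 in CSE-KO. With 2 libraries against 2, a two-sided exact permutation test cannot give a p below 0.333, and no test of list length was run.

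Where the counts of a library fell differed between marks, with each library's own list included in the share of its mark. H3K23ac libraries placed 94.9% ± 1.88 of their counts in regions of the H3K23ac lists, 2.48% ± 1 in H3K27ac lists and 2.66% ± 0.906 in H3K4me3 lists (SD, n = 4). H3K27ac libraries placed 45% ± 2.88 in H3K23ac lists, 47.2% ± 3.48 in H3K27ac lists and 7.79% ± 0.717 in H3K4me3 lists, and H3K4me3 libraries 50.9% ± 5.51, 9.42% ± 2.11 and 39.7% ± 7.6 (SD, n = 4 each). The library's own list, which favours it, held 85% ± 5.8 of the counts in H3K23ac libraries. It held 20.4% ± 13.9 in H3K27ac and 22.9% ± 11.2 in H3K4me3 libraries (SD, n = 4 each). Between genotypes, H3K27ac libraries held 44.6% ± 1.8 of their counts in H3K27ac lists in WT and 49.8% ± 2.52 in CSE-KO (SD, n = 2 each). Of their counts, the library's own list held 12.5% ± 2.3 in WT and 28.3% ± 18 in CSE-KO. H3K4me3 libraries held 43.2% ± 11.1 in H3K4me3 lists in WT and 36.1% ± 0.436 in CSE-KO, a difference smaller than the WT spread.

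**Figure D1:**
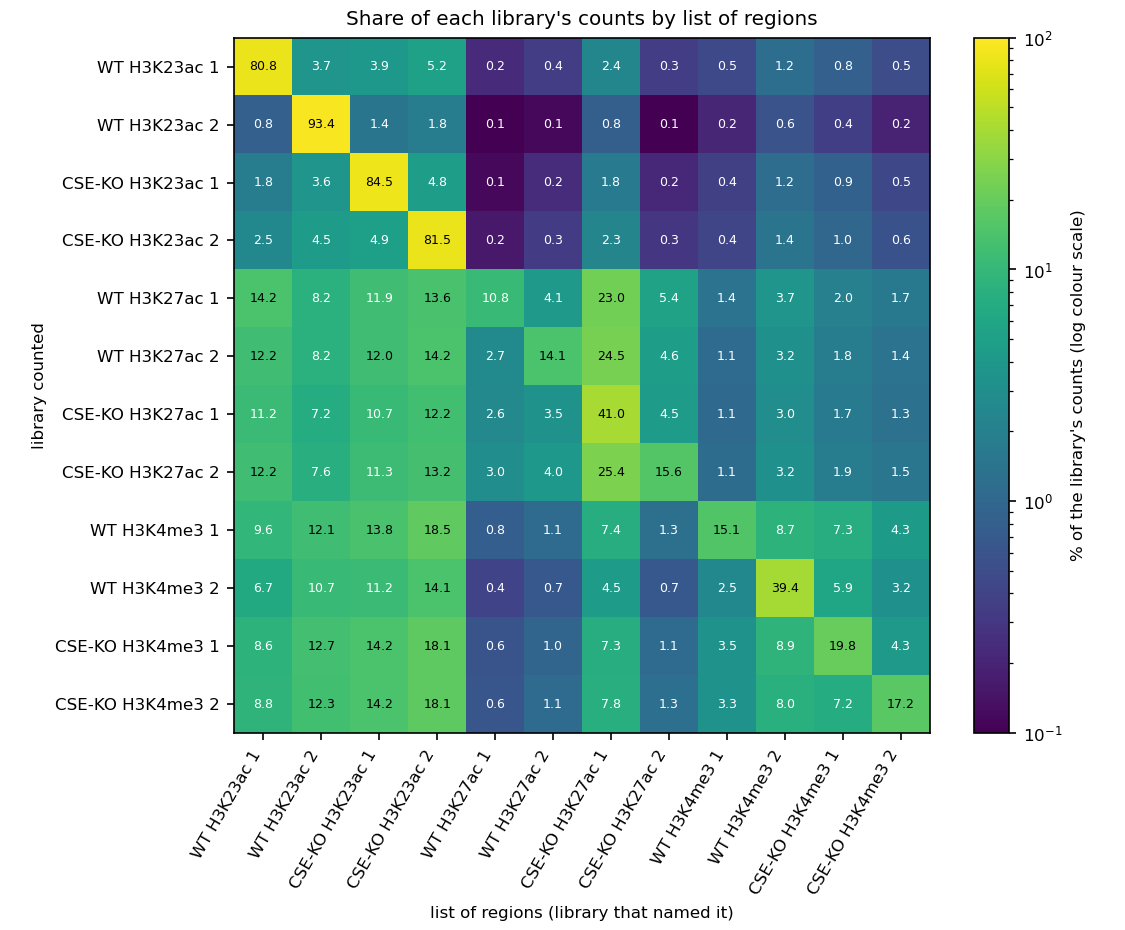
Percentage of each library's counts (rows) that fell in each list of regions (columns, named by the library that the list belongs to), with a logarithmic colour scale. In each column the highest share is that of the library the list belongs to, up to 93.4% in WT H3K23ac replicate 2, while H3K27ac and H3K4me3 libraries also spread over the H3K23ac lists.

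Libraries of H3K27ac resembled each other across regions, and so did those of H3K4me3, whereas those of H3K23ac did so much less. Over regions with a count in any library, the rank correlation had a median of 0.444 over the 6 pairs of H3K27ac libraries (0.369 to 0.526) and of 0.374 for H3K4me3 (0.338 to 0.421), but of 0.0508 for H3K23ac (0.0177 to 0.0966). These correlations are across regions, which are not independent replicates, and the regions include each library's own list. The share of a library's counts on its own list ran from 80.8% (Wilson 95% interval 80.8 to 80.9) to 93.4% (93.4 to 93.5) among the H3K23ac libraries, and was 10.8% (10.8 to 10.9) in WT H3K27ac replicate 1. Replicates of the same genotype and mark correlated about as well as libraries of different genotypes, with medians of 0.448 and 0.444 for H3K27ac and 0.38 and 0.374 for H3K4me3.

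H3K23ac was compared between CSE-KO and WT to ask whether the acetylation mark moved without CSE. No region passed the threshold of edgeR's quasi-likelihood test, 0 of 12365 regions tested, with 651 at an unadjusted p under 0.05 (419 higher and 232 lower in CSE-KO, 5.26% of those tested) and a lowest adjusted p of 0.637. Regions of the 2 WT H3K23ac lists had a median log2 fold change of -1.32 (4348 regions) and regions of the 2 CSE-KO H3K23ac lists one of 1.32 (6372 regions). Those lists follow the libraries that are compared, and in regions of the H3K27ac and H3K4me3 lists the median was 0.07 for WT lists (694 regions) and 0.12 for CSE-KO lists (951 regions). DESeq2 called 110 regions, 2 higher and 108 lower in CSE-KO, and edgeR with all 12 libraries in the model called 10. The biological coefficient of variation was 160%, and in simulated data with this spread the test recovered 0 of 50 regions changed 16-fold, so changes of that size were not detectable here. The scaling also set the level: the median log2 fold change of all tested regions was 0.21 with TMM factors, 0.75 with total counts and 0.04 with DESeq2 size factors. Fits that left out a library tested more regions and called 53 without WT replicate 1, 22 without WT replicate 2, 5 without CSE-KO replicate 1 and 9 without CSE-KO replicate 2.

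H3K27ac changed at 3 of 10666 tested regions in CSE-KO, rising at 2 and falling at 1. The region peak9_212007 had no count in either WT library and 91 and 30 counts in CSE-KO, or 209 ± 15.3 CPM (counts scaled to the library, SD, n = 2), at least 17.5-fold higher than the floor of 3 counts over the WT group (edgeR adjusted p = 0.0299). The region peak9_158291 likewise went from no count to 108 and 22 counts, or 199 ± 52.5 CPM, at least 16.6-fold higher (edgeR adjusted p = 0.0299). Both belong to the list of CSE-KO H3K27ac replicate 1, the deepest library. The region peak1_20257, from the list of WT H3K23ac replicate 1, fell from 187 ± 2.13 to 10.2 ± 4.07 CPM (SD, n = 2 each), with a log2 fold change of -3.96 and a standard error of 0.59 (edgeR adjusted p = 0.0299). It had 22 and 25 counts in WT and 6 and 1 in CSE-KO.

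Across all tested regions the H3K27ac log2 fold changes had a median of 0.00 and an SD of 0.69. TMM scaling sets most folds near 0, so this median does not test for an overall change. It was 0.06 with total counts and -0.03 with DESeq2 size factors. In the edgeR test 482 regions had an unadjusted p under 0.05, 215 higher and 267 lower, or 4.52% of those tested, and with scaling by total counts the split was 201 higher and 162 lower. Regions of the WT H3K27ac lists had a median log2 fold change of -0.71 (557 regions) and those of the CSE-KO H3K27ac lists one of 0.26 (4810 regions), while regions of the other marks' lists had medians of -0.18 for WT lists (2092 regions) and -0.17 for CSE-KO lists (3207 regions). In simulated data with 200 changed regions, the test recovered 2% of those changed 2-fold and 36% of those changed 4-fold. It recovered 86% of those changed 8-fold and 98% of those changed 16-fold. The adjusted p depends on how many regions change, and recovery with few changed regions may be lower and was not simulated. The rates therefore do not show that further 8-fold or 16-fold changes were absent. The 3 calls were lost with total-count scaling and with DESeq2 (0 regions each, with 363 and 166 of 10666 at an unadjusted p under 0.05). They were also lost with all 12 libraries in the edgeR model (0 regions, with 64 of 48016 at an unadjusted p under 0.05). That model had a biological coefficient of variation of 1.03, against 0.344 in H3K27ac alone, which left it less able to call changes in this mark. In regions of the other marks' lists 1 call remained. The number of calls was 59 without WT replicate 1, 135 without WT replicate 2, 2 without CSE-KO replicate 1 and 7 without CSE-KO replicate 2, and these held 3, 2, 1 and 2 of the 3 regions.

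**Figure D2:**
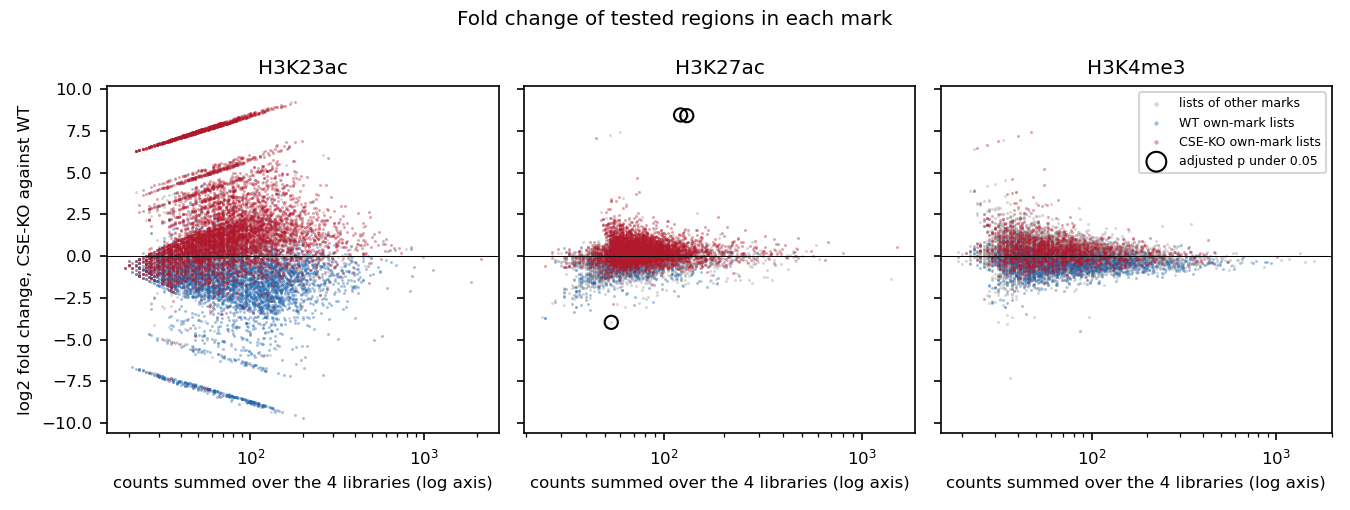
Log2 fold change of CSE-KO against WT (vertical axis) against the counts summed over the 4 libraries of the mark (horizontal log axis), 1 point per tested region, for 12365 H3K23ac, 10666 H3K27ac and 10960 H3K4me3 regions. Colours give the list a region belongs to, and the 3 circles are the H3K27ac regions past an adjusted p of 0.05. The parallel bands of H3K23ac are regions with no count in either library of 1 genotype, where the fitted fold depends on the prior count.

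H3K4me3 did not change past the threshold at any of 10960 tested regions. The edgeR test gave 0 calls and 475 regions at an unadjusted p under 0.05, 247 higher and 228 lower in CSE-KO, or 4.33% of those tested, and DESeq2 also called 0, with 187 at an unadjusted p under 0.05. With scaling by total counts the unadjusted split was 369 higher and 116 lower, and the median log2 fold change of all regions moved from -0.02 to 0.12. The region nearest to the threshold, peak6_18659 of the list of WT H3K4me3 replicate 2, had 25 and 58 counts in WT and 3 and 1 in CSE-KO, or 198 ± 78.2 and 8.09 ± 4.28 CPM (SD, n = 2 each). Its log2 fold change was -4.47 with a standard error of 0.7 and an edgeR adjusted p of 0.0611. Regions of the WT H3K4me3 lists had a median log2 fold change of -0.43 (1830 regions) and those of the CSE-KO H3K4me3 lists one of 0.26 (1871 regions), against -0.01 and 0.02 in WT and CSE-KO lists of the other marks (2614 and 4645 regions). In simulated data with 200 changed regions, changes were recovered at 2% for 2-fold, 24% for 4-fold, 84% for 8-fold and 94% for 16-fold. The adjusted p depends on how many regions change, and recovery with few changed regions may be lower and was not simulated. In the real data peak6_18659, with a log2 fold change of -4.47, did not pass. The rates therefore do not show that 8-fold or 16-fold changes were absent. Fits without 1 library called 305 regions without WT replicate 1, 15 without WT replicate 2, 3 without CSE-KO replicate 1 and 1 without CSE-KO replicate 2.

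**Figure D3:**
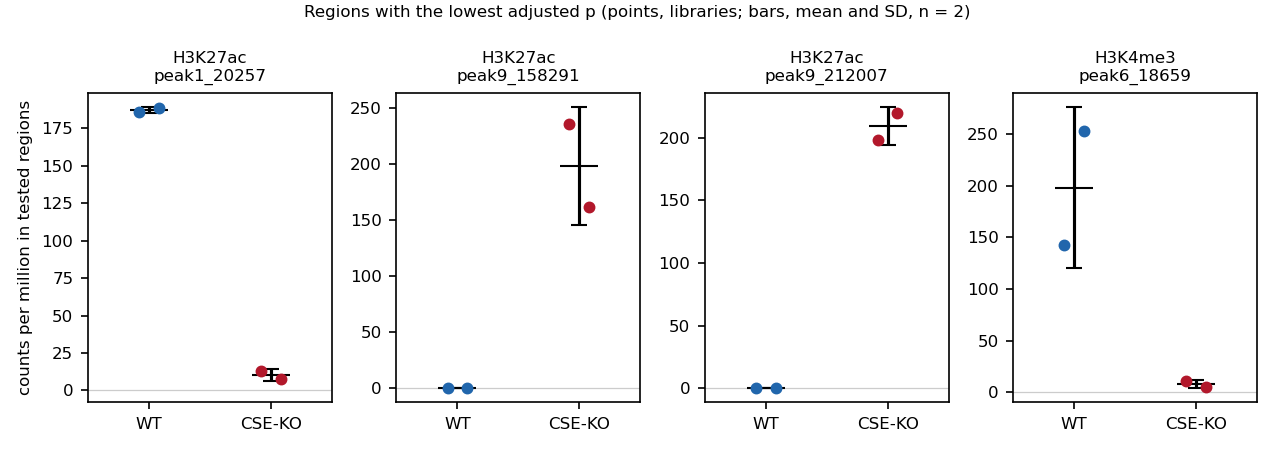
CPM in tested regions (vertical axes, with a line at 0) of the 3 called H3K27ac regions and of the H3K4me3 region with the lowest adjusted p, in WT and CSE-KO. Points are libraries and bars are the mean with its SD (n = 2). The 2 libraries of each genotype lie apart from those of the other in all 4 panels, which for a single region taken by itself has a two-sided exact permutation p of 0.333.

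Whether the genotype effect differed between marks was tested as an interaction in a model of all 12 libraries over 48016 regions. The effect on H3K23ac differed from that on H3K4me3 at 6 regions, 3 in each direction, and from that on H3K27ac at 4 regions, 1 higher and 3 lower (edgeR, lowest adjusted p of 1.35e-05 and 4.3e-05). In 4 of the 6 and 3 of the 4 regions, over 90% of the H3K23ac counts came from 1 library. A region from the list of CSE-KO H3K4me3 replicate 1, where they did not, was called in both contrasts: H3K23ac counts were 0 and 0 in WT and 91 and 81 in CSE-KO, while H3K4me3 counts were 191 and 284 in WT and 323 and 216 in CSE-KO, and H3K27ac counts 28 and 35 in WT and 117 and 31 in CSE-KO. The other region called in both, of the WT H3K23ac replicate 2 list, had all of its 780 H3K23ac counts in that library. The effects on H3K27ac and H3K4me3 differed at 0 regions by edgeR, with 304 at an unadjusted p under 0.05, and at 0 by DESeq2, with 31. DESeq2 called 8 regions for H3K23ac against H3K4me3, 1 higher and 7 lower, of which only 2 were among the 6 called by edgeR. For H3K23ac against H3K27ac it called 1 region, which was among the 4 called by edgeR. With TMM factors computed within each mark, edgeR called 3 and 1. The model used 1 spread for all marks, with a biological coefficient of variation of 1.03, against 1.6 in H3K23ac, 0.344 in H3K27ac and 0.37 in H3K4me3 fitted alone. In the H3K23ac contrasts 15.3% and 18.3% of regions had an unadjusted p under 0.05, against 0.633% for H3K27ac and H3K4me3. The p-values of the H3K23ac contrasts may therefore be too low, and those of H3K27ac against H3K4me3 too high. In edgeR models of the 8 libraries of the compared marks alone, H3K23ac differed from H3K4me3 at 1 region and from H3K27ac at 0, with 2433 and 3653 at an unadjusted p under 0.05, and H3K27ac and H3K4me3 differed at 0 of 20943, with 985 (4.7%). The contrast with H3K4me3 gave 0 calls without CSE-KO H3K4me3 replicate 1 (6198 at an unadjusted p under 0.05), 3 without replicate 2 of either H3K4me3 genotype, 110 and 19 without WT H3K23ac replicates 1 and 2, and 2 and 1 without CSE-KO H3K23ac replicates 1 and 2. The contrast with H3K27ac gave 0 calls without CSE-KO H3K23ac replicate 2 (26011 at an unadjusted p under 0.05), 2 without its replicate 1, 83 and 22 without WT H3K23ac replicates 1 and 2, 1 without either WT H3K27ac library and 8 without either WT H3K4me3 library.

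The fold changes of H3K27ac and H3K4me3 were weakly correlated across regions tested in both. Spearman's coefficient was 0.16 (bootstrap 95% interval 0.104 to 0.212) and Pearson's 0.187 over 1211 regions, of which 55.6% had the same sign in both marks. In the regions of H3K23ac lists alone, which neither mark's libraries had named, Spearman's coefficient was 0.151 (0.0861 to 0.217, 848 regions). For H3K23ac and H3K4me3 the coefficient was 0.0578 (0.0273 to 0.0877, 4310 regions, Pearson's 0.0666), and for H3K23ac and H3K27ac 0.0429 (0.0013 to 0.0817, 2643 regions, Pearson's 0.0756), where 48.6% of regions had the same sign. For the latter pair Spearman's coefficient in regions of the H3K4me3 lists was -0.114 (-0.292 to 0.0659, 125 regions). In regions with a mean CPM at or above the median, Spearman's coefficient was 0.245 for H3K27ac and H3K4me3 (0.133 to 0.345, 306 regions), 0.093 for H3K23ac and H3K4me3 (0.039 to 0.148, 1329 regions) and 0.081 for H3K23ac and H3K27ac (0.0147 to 0.153, 793 regions). These correlations are across regions, which are not independent replicates, and the intervals cover the sampling of regions, not of animals. With edgeR, 0 regions were called in both marks of any pair, out of 3 called for H3K27ac and 0 for each of the other marks.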

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

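The interaction test was planned on promoters and run on regions. Its fit on 8 libraries and the tests of total depth and of counting noise were chosen after the result was seen. The test of complexity took the place of earlier ones after the pattern was seen, with its prediction set before its own result.

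The edgeR interaction test of 12 libraries called 6 regions for H3K23ac against H3K4me3 and 4 for H3K23ac against H3K27ac. Its 1 spread for all marks, a biological coefficient of variation of 1.03, lay below the 1.6 of H3K23ac fitted alone. The p-values of both contrasts may therefore be too low, with 15.3% and 18.3% of regions at an unadjusted p under 0.05. With TMM factors computed within each mark the counts of called regions were 3 and 1. With the 8 libraries of the compared marks alone they were 1 and 0 (edgeR, 2433 and 3653 regions at an unadjusted p under 0.05). The first count came to 0 without CSE-KO H3K4me3 replicate 1 and the second to 0 without CSE-KO H3K23ac replicate 2 (edgeR, 6198 and 26011 regions at an unadjusted p under 0.05). Besides the region of the CSE-KO H3K4me3 replicate 1 list described above, a region of the WT H3K4me3 replicate 2 list was called against H3K4me3. It had H3K23ac counts of 0 and 3 in WT and 162 and 95 in CSE-KO, and H3K4me3 counts of 137 and 336 in WT and 251 and 168 in CSE-KO (edgeR adjusted p = 0.00594). In 4 of the 6 and 3 of the 4 regions over 90% of the H3K23ac counts came from 1 library, as in a region of the WT H3K23ac replicate 2 list with 780 counts in that library and 0 in the other 3 of the mark. That region, too, was called in both contrasts.

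A pattern that bears on these calls is that the 4 H3K23ac libraries shared few regions. Fewer counts in total were not the cause, since the shallowest H3K23ac library held 1466588 counts and the deepest H3K4me3 library 563755. Outside their own lists the H3K23ac libraries held fewer, 121576 to 300789 against 336419 to 451904 for H3K4me3. If each count is an independent molecule, counting noise outside the own lists was not the whole cause. With Poisson noise removed, in regions of the other marks' lists, which differ by mark, the median correlation of H3K23ac pairs was 0.355 (0.274 to 0.485). This lay below the lowest pairs of H3K27ac (0.761) and H3K4me3 (0.873). Noise from few molecules read many times would remain after the removal, so the test cannot exclude it. Low complexity, that is few molecules each read many times, stays open. It would make regions with exactly 1 count rare. Among counted regions of the H3K27ac lists these were 35% to 45.0% in H3K23ac libraries and 37.5% to 54.3% in H3K4me3 libraries. The ranges overlap through WT H3K4me3 replicate 2 (37.5%), while the other H3K4me3 libraries had 49.4%, 50.3% and 54.3%. The mean count of the counted regions was 4.05 to 7.21 in H3K23ac and 2.12 to 3.16 in H3K4me3 libraries. Because of the overlap the test does not decide. A weak antibody signal and a biological difference between animals stay open and untested. So does the loss of reads that overlap regions of several lists, which would remove shared regions from the counts.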

How the results depend on the processing

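The 8-library models, the lists of other marks, the lists of the remaining mark and the joint genotype term were chosen after the data had been seen.

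For H3K23ac (0 calls), size factors, total counts, the replicate block, the fold minimum and the other marks' lists left 0, while no filter gave 1, DESeq2 110, all 12 libraries 10, and leaving out a library 5 to 53. For H3K27ac (3 calls), total counts, DESeq2 and all 12 libraries gave 0, the other marks' lists 1, no filter and the median filter 5 (the same 606015 regions), the replicate block 5 and leaving out a library 2 to 135. For H3K4me3 (0 calls), no filter gave 10, leaving out a library 1 to 305, and the other 7 alternatives, the replicate block included, 0. The median filter gave no value for H3K23ac and H3K4me3, whose median was 0. A fit without a library leaves 1 library in a group, assumed to vary like the others, and the filter then needs counts in 1 library, so 13468 to 125399 regions were tested; the cause of the other changes was not tested.

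The interaction of H3K23ac with H3K4me3 (6 calls) gave 8 with DESeq2, of which 2 were among the 6, and 3 with TMM within marks. It gave 1 with the 8 libraries of both marks only, 0 with the replicate block and 0 to 110 without a library. That with H3K27ac (4 calls) gave 1 with TMM within marks, 1 with DESeq2, 0 with the 8 libraries of both marks only, 0 with the replicate block and 0 to 83 without a library. H3K27ac against H3K4me3 gave 0 in 16 alternatives, which says little of stability for those whose spread includes H3K23ac (0.633% of regions at an unadjusted p under 0.05 with all 12 libraries, 4.7% with the 8). In regions of the remaining mark's lists the correlation of fold changes turned to -0.114 for H3K23ac and H3K27ac and was 0.0644, with an interval that includes 0, for H3K23ac and H3K4me3; there were 125 and 147 regions. The joint genotype term over H3K27ac and H3K4me3 (7 calls) gave 10 with the replicate block, 5 to 11 without a library and 0 with all 12 libraries.

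Whether replicate numbers pair the libraries is not shown: same-numbered libraries had correlated deviations of -0.00878 in H3K23ac, -0.0885 in H3K27ac and -0.0644 in H3K4me3. Alternatives for promoters, gene lists, Cth, distal regions and autosomes were not run. At the depth and spread of these libraries, simulated 2-fold changes were recovered at 0% in H3K23ac and 2% in H3K27ac and in H3K4me3.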

Other observations

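The joint genotype term was added and its splits within marks were chosen after the data had been seen, and the patterns of lists and of empty regions were noticed in the same data that their tests used. The reading of the test of empty regions was changed after its result was seen.

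Some regions differed between genotypes on average over H3K27ac and H3K4me3, which does not require a change in both marks. A model of the 8 libraries of these marks, with a term for the mark and a term for the genotype, called 7 of 20943 regions, 6 higher and 1 lower in CSE-KO (edgeR, lowest adjusted p of 0.00221). They include the 3 regions called for H3K27ac alone, of which the 2 rising ones had no count in any H3K4me3 library. A region from the list of CSE-KO H3K23ac replicate 1 had no count in any of the 6 WT libraries, and in CSE-KO 67 and 7 counts in H3K23ac, 41 and 12 in H3K27ac and 11 and 6 in H3K4me3. A region from the list of CSE-KO H3K4me3 replicate 1 had sums over 6 libraries of 3 counts in WT and 119 in CSE-KO, and 2 regions from the list of CSE-KO H3K23ac replicate 2 had sums of 3 and 107 and of 76 and 450, with counts in all 6 CSE-KO libraries each. All 6 rising regions thus belong to lists of CSE-KO libraries, and the sums include the library that the list belongs to, with 67 of 144 counts in the region first described and 36 of 119, 46 of 107 and 81 of 450 in these 3. That library gave 91 of 121 and 108 of 130 counts in the 2 rising regions with counts in H3K27ac alone. The falling region, peak1_20257, from the list of WT H3K23ac replicate 1, had 129 counts over 5 of the 6 WT libraries, 53 of them in that library, and 9 over 3 of the 6 CSE-KO libraries. H3K23ac libraries took no part in these calls.

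Of the 34 splits of these 8 libraries that the model can fit, 1 gave 7 or more calls, the real one, and the highest of the others gave 5. Of these splits 16 put 3 libraries of a mark against 1 and do not compare with the real one. The other 18 keep 2 libraries of each mark on each side, and 1 of 18 is a share of 0.0556, so they are too few for a share under 0.05. The split with 5 calls put replicates numbered 1 against those numbered 2. Without WT H3K27ac replicate 1 the genotype term gave 11 calls. With all 12 libraries, and so with H3K23ac in the fit, edgeR gave 0 calls, and 1402 of 48016 regions at an unadjusted p under 0.05. If libraries of different marks came from the same animals, they may not be independent, and differences between animals in sex or background would appear alike in every mark. Neither was tested, since regions carry no position.

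Lists called in CSE-KO took a larger share of the counts in CSE-KO libraries of the other marks. The ratio of counts in the CSE-KO lists to counts in the WT lists of H3K27ac was 5.43 ± 0.36 in CSE-KO and 4.49 ± 0.26 in WT H3K23ac libraries, and 5.31 ± 0.15 and 4.67 ± 0.19 in H3K4me3 libraries (SD, n = 2 each), which is 20.9% and 13.7% higher in CSE-KO. The other differences were 12.2% for H3K23ac libraries over H3K4me3 lists, 3.8% for H3K27ac libraries over H3K4me3 lists, 3.52% for H3K4me3 libraries over H3K23ac lists and 2.3% for H3K27ac libraries over H3K23ac lists, where the genotypes overlapped. Both CSE-KO libraries lay above both WT libraries in 5 of 6 pairs of marks, where chance gives 16.7% each, with a mean log2 difference of 0.127. The 6 pairs reuse the same libraries and are not independent. In an exact permutation test within marks, 3 of 108 regroupings gave a difference as large (two-sided p = 0.0278). This test takes libraries of different marks as independent, and the labels do not say whether the marks share animals. If they do, this p-value may be too low. The highest difference of the other regroupings, 0.131, exchanged an H3K27ac library of each genotype. The difference stayed above 0 without each library and the list it named, from 0.0647 without WT H3K27ac replicate 1 to 0.219 without WT H3K27ac replicate 2. Its sign thus did not rest on 1 library. The reduced sets had no test, so how far its size rests on the H3K27ac libraries stays open. A few stretches of regions were not the whole cause, as the median over 20 blocks of consecutive regions was 0.139 (bootstrap 95% interval 0.0919 to 0.188), with 17 blocks above 0. A genotype difference shared by the marks is a candidate explanation, and animals shared between marks, their sex and the counting of overlapping reads stay open and untested.

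Many regions had no count even in the library that named their list, from 42.4% in the list of WT H3K23ac replicate 1 to 76.3% in that of WT H3K27ac replicate 1. In 12 of 12 lists, regions empty in their own library were also empty in the other 11 libraries more often than regions with counts were, 47.2% to 95.5% of them against 2.95% to 8.81%. Reads left out because they overlap regions of more than 1 list would give this, and so would reads lost for another reason, such as poor mappability or a difference in build, so these cannot be told apart here. No biological explanation was tested.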
